A study of Mus musculus with 33 samples.

How the data were processed

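Ribosome-depleted total RNA of CH12 cells was sequenced as stranded, single-end libraries, per the labels. The submitters' processing notes name kallisto 0.43.0, DESeq2 and the mouse build GRCm38.p5. The annotation release, the index options and the strand setting are not given in the sources used here. The authors deposited 1 table per library, with estimated counts (expected counts, not whole, not normalized) and TPM values for each of 171152 targets: 121400 Ensembl transcripts, 49745 numbered genomic regions of 251 to 20296 bases (median 697) and 7 Igh elements. The deposited TPM values were not used. Reads are shared between similar targets by kallisto's model, so counts of near-identical elements such as hs3a and hs3b depend on each other, and a region that overlaps a transcript can lose reads to it. Effective lengths were equal in all libraries, so a length-scaled alternative would return the counts and was not run. A single region holding the 7SL RNA took between 2.01% and 3.47% of a library's counts.

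Estimated counts were rounded and scaled by the trimmed mean of M values. Targets were kept by edgeR's filterByExpr by group, which left 49806 transcripts, 11264 regions and 4 Igh elements. All 24 libraries entered 1 edgeR quasi-likelihood model (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with 8 group means. The contrasts were KO lines against WT lines in each state, activation in each genotype, their difference, and the pairs of lines of one genotype. A target was called when its Benjamini-Hochberg adjusted p, taken over the targets of the fit, was under 0.05. The same model was fitted to gene values. No table linking transcripts to genes was used here, so a gene value is the sum of regions wholly inside the span of exactly 1 RefSeq gene of GRCm38.p6; 26591 of the regions lie so, 18754 lie outside genes, and 4400 overlap a gene end or several genes. The annotation entries that span whole loci, 12 in number, were left out. This gave 10750 gene values, of which 4485 passed the filter. Region positions are those in the tables, counted from 1.

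The named genes follow a rule fixed before the data were examined: the 10 highest and the 10 lowest log2 changes among called genes with at least 5 CPM in a group compared, not Gm or Rik named, and of equal sign in each line or line pairing. To these were added Zmynd8, the Igh constant genes, and up to 4 members of each called list with the smallest p. Its application to region sums was a fallback, as the rule was written for whole genes. Some genes that the rule selects are not reported here. The Igh targets and their sums were chosen after the data were examined and tested by exact permutation of 6 against 6 libraries, which takes the cultures of a line as independent. Their ratios carry 95% exact counting intervals, with a floor of 3 counts over the group where a group had 0 counts.

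For gene lists, 24 were fixed beforehand, 16 had at least 5 measured members, and limma's camera with a preset correlation of 0.01 tested them in 5 comparisons, 80 tests adjusted together. All 10 calls were lost with an estimated correlation. On simulated data of the same size with 100 targets changed per fold, 47% of 2-fold and 82% of 4-fold changes were called, with 3.01% false calls. For gene values these were 82%, 100% and 3.70%. The changed targets were drawn from those above the median level, so the shares do not apply to lower ones. No other differences between lines were simulated, so the false calls do not cover these.

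Replicate libraries differed by more than sampling noise, with a chi-square per degree of freedom of 9.945 to 67.22, so none was counted as a repeat of another. The labels call the 3 cultures of a group biological repeats and say nothing more on how far they are separate. The alternatives tried were relative log expression scaling, DESeq2 1.42.0, no low-count filter, a block for the replicate number, counts summed per line, only the libraries of a comparison, a 2-group fit, each line alone, each library left out in turn, and, chosen after the data were examined, leaving out 2 or 3 libraries that stand apart. A change of 0.05 in the correlation between KO1 and KO2 effects was taken as the limit for an unchanged value, a limit chosen after the values were seen. The share of Igha in Igh constant counts and the fit restricted to protein-coding genes, both planned, were not run, since they need whole-gene counts. To save time, 40 splits of the libraries were drawn per main comparison, and not 100. The result of every list tested is printed once in the results, by its call or its lowest adjusted p.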

Results

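Total RNA was sequenced from CH12 cells, a mouse B lymphoma line that carries IgM on its surface and switches to IgA when it is stimulated. The lines compared were parental wild type (WT), a WT clone, and 2 lines, KO1 and KO2, lacking ZMYND8, a chromatin reader that binds modified histone tails through its PHD, bromo and PWWP domains. Each of the 4 lines was cultured for 48 h unactivated or activated, with 3 cultures per line and state, which gave 24 libraries in 8 groups of 3. The labels do not name the activating stimulus. Another 9 samples of the series, 8 from ChIP-seq and 1 from GRO-seq, were not analysed here. Sequencing depth, as the total estimated count per library, ranged from 28.99 to 34.07 M, with a median of 32.1 M. Transcripts took between 94.5% and 96.2% of it, and numbered genomic regions between 3.78% and 5.48%. The tables held 121400 transcripts, numbered regions of 251 to 20296 bases and 7 named elements of the immunoglobulin heavy chain (Igh) locus. Values of a named gene below are the summed counts of all regions lying wholly inside its span, so they describe RNA from part of the gene, with exon, intron and strand unknown, and not its mature mRNA. Levels are depth-scaled counts (CPM), given as mean ± SD with n = 6 (3 cultures of each of 2 lines) unless stated, and log2 changes are given with their standard error.

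The series asks how ZMYND8 acts on the Igh enhancers, so RNA from the 3' regulatory region, the enhancer cluster downstream of the Igh constant genes, was compared first. The choice of these targets was made after the data were examined. RNA summed over 5 regions between positions 113215821 and 113254334 of chromosome 12 (GRCm38) and the 4 named enhancer elements hs3a, hs12, hs3b and hs4 was higher in the KO lines in both states. In unactivated cells it was 25.9 ± 4.00 CPM in KO and 5.65 ± 1.15 CPM in WT, a ratio of 4.58. In activated cells it was 31.6 ± 8.01 CPM in KO and 7.09 ± 0.975 CPM in WT, a ratio of 4.46. All 6 KO libraries lay above all 6 WT libraries in each state, with an exact 2-sided permutation p of 0.00216, the smallest that 6 against 6 can give, and 0.00346 after adjustment over 8 tests of Igh sums. By line, the unactivated means were 6.49 ± 1.11 CPM in parental WT, 4.82 ± 0.112 CPM in the WT clone, 25.5 ± 4.51 CPM in KO1 and 26.3 ± 4.36 CPM in KO2 (n = 3 each).

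**Figure D1:**
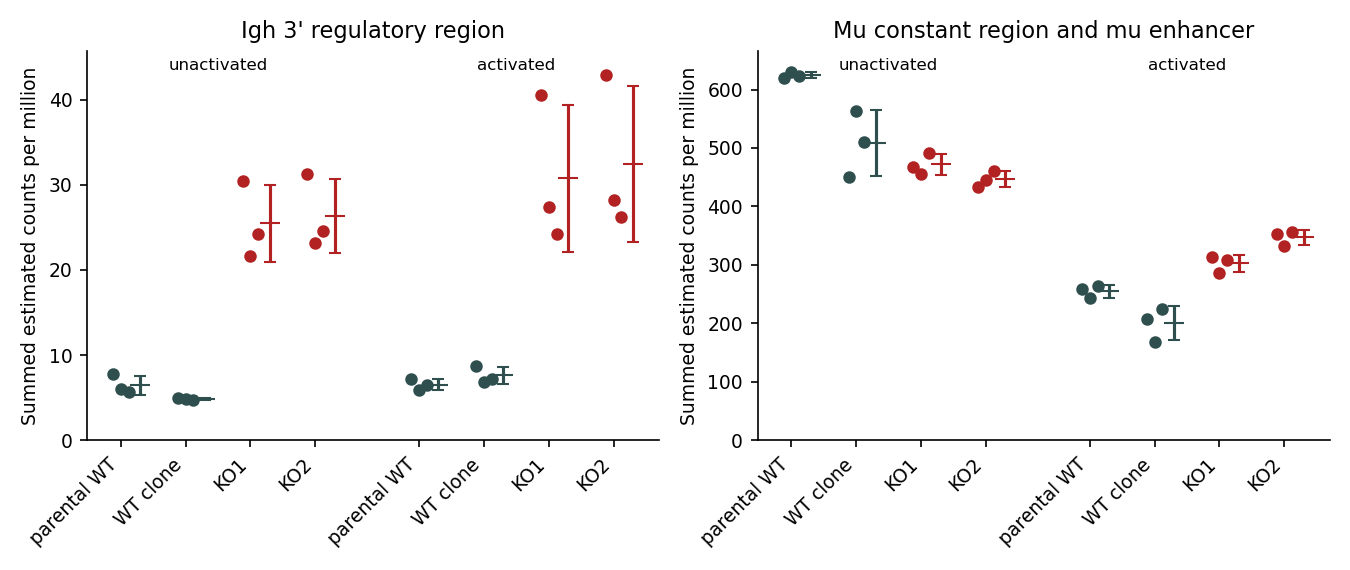
Summed counts (CPM) of the Igh 3' regulatory region (left) and of the mu constant region, switch region and enhancer (right) in each library. Points are the 3 cultures of a line, and bars the mean ± SD of those 3. The KO libraries sit between 21.7 and 31.3 CPM for the 3' regulatory region in unactivated cells, and the WT libraries between 4.70 and 7.76 CPM.

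The parts of the 3' regulatory region differed in size of change. The part from 113235821 to 113237901 had 1143 counts over the 6 unactivated KO libraries and 54 over the 6 WT libraries, a ratio of 20.1 (95% counting interval 15.3 to 27.0). In activated cells its ratio was 12.6 (10.4 to 15.4). The farthest part, from 113215821 to 113232872, differed 2.11-fold (1.92 to 2.32) in unactivated and 2.84-fold (2.59 to 3.11) in activated cells. The hs3b element had 163 counts in unactivated KO against 7 in WT, a ratio of 22.2 (10.5 to 56.0), and 131 against 2 in activated cells, a ratio of 66.2 (17.96 to 552). Reads of the near-identical hs3a and hs3b are shared by kallisto's model, so the separate values of each depend on that split. For hs3a the counts were 133 in KO against 63 in WT in unactivated cells, and 212 against 169 in activated cells. The pair was not tested as a sum. The hs3a element rose by a log2 change of 0.99 ± 0.23 in unactivated KO cells (adjusted p = 0.00884), and in activated cells its value was 0.33 ± 0.22 (adjusted p = 0.533). The unactivated call was lost against the WT clone alone (0.90), with counts summed per line (1.02) and in a fit of only the 12 unactivated libraries (1.02). With counts summed per line the calls were also lost for hs3b (log2 change 4.44) and the farthest part (1.10) in unactivated cells, and for the part from 113235821 (3.64) in activated cells. The hs4 element had at most 11 counts over any 6 libraries, and hs12, the mu switch intron and the region from 113253592 to 113254334 were listed at 0 in all 24 libraries. Intervals cover counting error only.

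At the constant genes the KO effect had both directions. The region over Ighm, which encodes the mu heavy chain (113418607 to 113429316), was lower in unactivated KO cells, 380 ± 28.0 against 531 ± 72.3 CPM, and higher in activated KO cells, 272 ± 21.3 against 169 ± 40.4 CPM. The fall rested largely on parental WT: against the WT clone alone its log2 change was -0.33 and not called, and neither change was called in all 4 pairings of lines. The mu enhancer element was higher in unactivated KO cells, 79.1 ± 11.8 against 35.1 ± 6.58 CPM, and in activated cells stood at 53.3 ± 6.96 against 58.7 ± 5.57 CPM (adjusted p = 0.60). No position is given for this element, so reads shared between it and the region over Ighm, which spans 10710 bases, are not excluded. Their opposite changes are thus not taken as separate effects. Counts were also summed over the region over Ighm, the mu switch intron and the mu enhancer. This sum leaves out reads assigned to annotated Ighm transcripts, which were not identified, so it does not measure mu mRNA. Summed mu counts were 459 ± 20.0 CPM in KO and 566 ± 73.3 CPM in WT without activation (exact permutation p = 0.0108, adjusted p = 0.0144), and 325 ± 27.2 against 228 ± 35.7 CPM with it (exact permutation p = 0.00216, adjusted p = 0.00346). By line, the means without activation were 625 ± 5.11 CPM in parental WT, 508 ± 56.9 in the WT clone, 472 ± 17.975 in KO1 and 446 ± 13.8 in KO2 (n = 3 each), so the WT lines lay farther apart than the WT clone and either KO line. With activation they were 255 ± 11.2, 200 ± 28.6, 303 ± 14.4 and 347 ± 13.2 CPM. The region inside Igha, the alpha constant gene (113257093 to 113257733), was higher in unactivated KO cells, 8.43 ± 0.401 against 4.64 ± 0.478 CPM, and stood at 9.12 ± 0.589 against 9.34 ± 1.08 CPM in activated cells. RNA near the gamma constant genes was lower in KO. A region 6513 bases from Ighg2b (113314446 to 113315182) had 0 counts in 6 unactivated KO libraries and 722 in WT, at least 253-fold lower against a floor of 3 counts over the group, and was 7.21-fold lower (6.38 to 8.18) in activated KO cells. A region 1049 bases from Ighg3 (113362281 to 113362926) had 1 count in unactivated KO and 78 in WT, and was 5.38-fold lower (3.13 to 9.83) with activation. The region overlapping Ighg1 (113320797 to 113329753) was 2.61-fold lower (1.65 to 4.24) and 3.56-fold lower (2.88 to 4.44) in the 2 states. With counts summed per line the activated calls near Ighg2b (log2 change -2.86) and Ighg3 (-2.41), both calls at Ighg1 (-1.36 and -1.84), both at Ighm (-0.46 and 0.68) and the unactivated call inside Igha (0.87) were lost. The unactivated call at Ighg1 was also lost in a fit of only the 12 unactivated libraries (-1.33). The alpha switch intron did not pass the test between genotypes in either state, with log2 changes of -0.52 ± 0.21 (adjusted p = 0.159) and 0.29 ± 0.20 (adjusted p = 0.572), but with KO2 alone it was called in unactivated cells (-1.12).

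**Figure D2:**
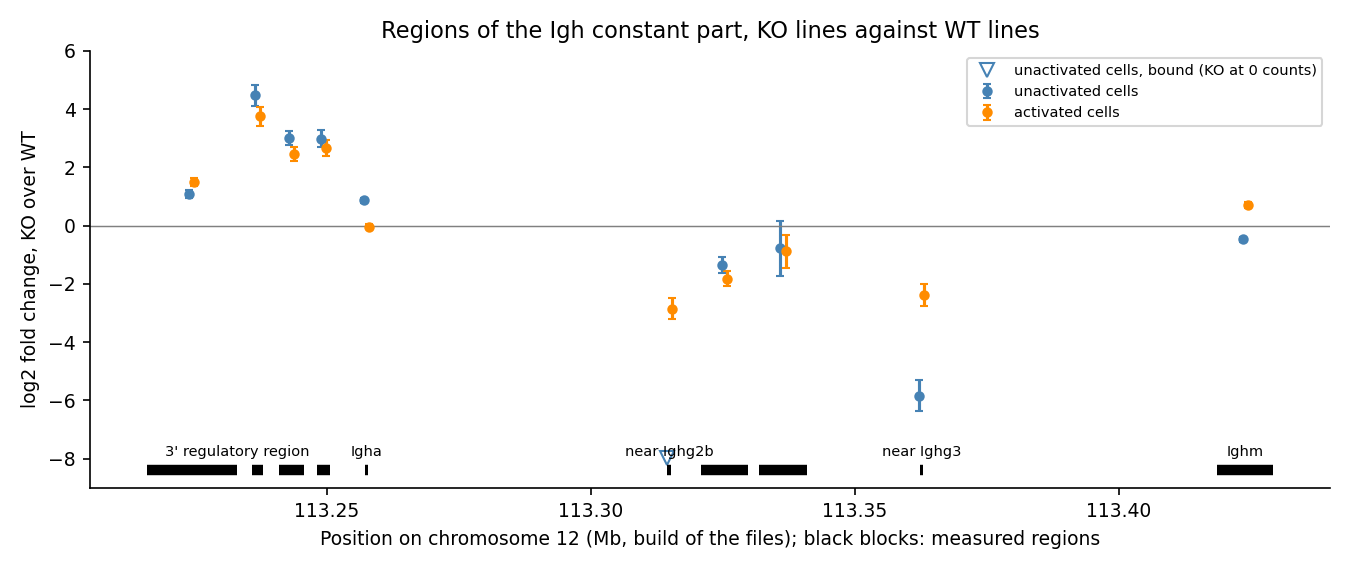
Fitted log2 change, KO over WT, of regions of the Igh constant part along chromosome 12 (Mb), in unactivated and activated cells. Bars are the standard error, black blocks the measured regions, and the open triangle is a bound for the region near Ighg2b, which had 0 counts in unactivated KO cells. Regions of the 3' regulatory region lie above 0 in both states and regions near Ighg2b, Ighg1 and Ighg3 below it, with no call for the region from 113331796 to 113341015.

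In unactivated cells, loss of ZMYND8 went with changes in both directions across the transcriptome: 1470 transcripts rose and 2159 fell of 49806 tested. Far fewer transcripts and regions were called with counts summed per line, as given below for the processing. Among the gene values with a mean of at least 5 CPM in a group, Glb1, the lysosomal beta-galactosidase, was 3.92-fold higher in KO (14.7 ± 2.52 against 3.71 ± 0.358 CPM, adjusted p = 1.95e-10). Ctnnbl1, a splicing-associated protein, rose 2.90-fold. Bach2, a repressor that holds back plasma cell differentiation, was at 8.55 ± 1.33 CPM in KO and 4.50 ± 1.26 CPM in WT. Tango6 fell most among them, 4.21-fold (3.48 ± 0.453 against 14.7 ± 3.53 CPM), followed by Fads2, a fatty acid desaturase, 3.73-fold lower, and Gas7, 2.80-fold lower. Colq, Ly6e, Tbc1d5, Prkce, Slc25a12 and Igha made up the other named rises, at log2 changes from 0.86 to 1.68. Ss18, Atp6v0e2, Gtpbp4, Entpd6, Gng7, Lrch1 and Lcp1 made up the other named falls, at -1.17 to -0.91. Of these, Gtpbp4, a nucleolar GTPase, lost its call on leaving out any of 5 of the 12 libraries, with log2 changes between -1.38 and -0.94. With KO1 alone the calls of Gtpbp4 (-0.80), Entpd6 (-0.83) and Prkce (0.75) were lost, and against parental WT alone those of Gtpbp4 (-1.09), Prkce (0.69) and Lcp1 (-0.64). Against the WT clone alone Gtpbp4 (-1.14) lost its call, with no low-count filter Gtpbp4 (-1.11) and Entpd6 (-1.06) did, and with counts summed per line both of these, Ctnnbl1 (1.57), Atp6v0e2 (-1.13) and Fads2 (-1.86) did. Of 11264 regions, 417 rose and 292 fell, and of 4485 gene values 151 rose and 137 fell. A change in the same direction in each of the 4 pairings of a KO with a WT line was called for 237 transcripts that rose and 393 that fell.

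In activated cells, 1491 transcripts were higher and 1679 lower in KO, while regions were mostly higher, with 633 up and 152 down. Here too, counts summed per line gave far fewer calls. Ms4a4a, a membrane protein of the CD20-related family, was 8.64-fold higher in KO (5.20 ± 1.80 against 0.601 ± 0.170 CPM, adjusted p = 8.5e-13). Adamts14, a procollagen-processing protease, was 4.37-fold higher (25.5 ± 6.65 against 5.91 ± 1.86 CPM). Tbc1d5 and Glb1 rose here as in unactivated cells, by 3.48 and 2.84-fold, and Ubxn11, Blk, Hvcn1, Snn and Abcc4 had log2 changes from 1.09 to 1.69. Fads2 was 4.29-fold lower (1.81 ± 1.10 against 6.99 ± 3.11 CPM). Il9r, the interleukin-9 receptor, was 2.80-fold lower, and Notch2, a receptor needed for marginal zone B cells, was 2.43-fold lower (7.18 ± 2.86 against 16.5 ± 3.05 CPM). Rab11fip3, Bcl2a1b, Sox5, Tango6, Pakap, Birc2 and Tmem154 had log2 changes from -1.21 to -0.87. Snn and Sox5 lost their calls on leaving out any of 5 and any of 6 of the 12 libraries, with log2 changes from 0.79 to 1.495 and from -1.44 to -0.73. Both also lost them in several other fits, among them against parental WT alone (0.67 and -0.67) and with KO1 alone (0.65 and -0.84). With KO1 alone the calls of Rab11fip3 (-0.72) and Tango6 (-0.62) were lost too, and with counts summed per line those of Rab11fip3 (-1.16), Notch2 (-1.21), Fads2 (-1.95), Blk (1.42), Snn (1.09) and Sox5 (-1.20). In all, 288 gene values were called higher and 109 lower. The KO changes overlapped between states: 631 transcripts rose in both, against 44.0 if the sets were independent, and 882 fell in both, against 72.8. The same lines are compared in both states, so lasting differences between lines unrelated to ZMYND8 would also give such an overlap. In each of the 4 line pairings, 286 transcripts were called higher and 256 lower.

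**Figure D3:**
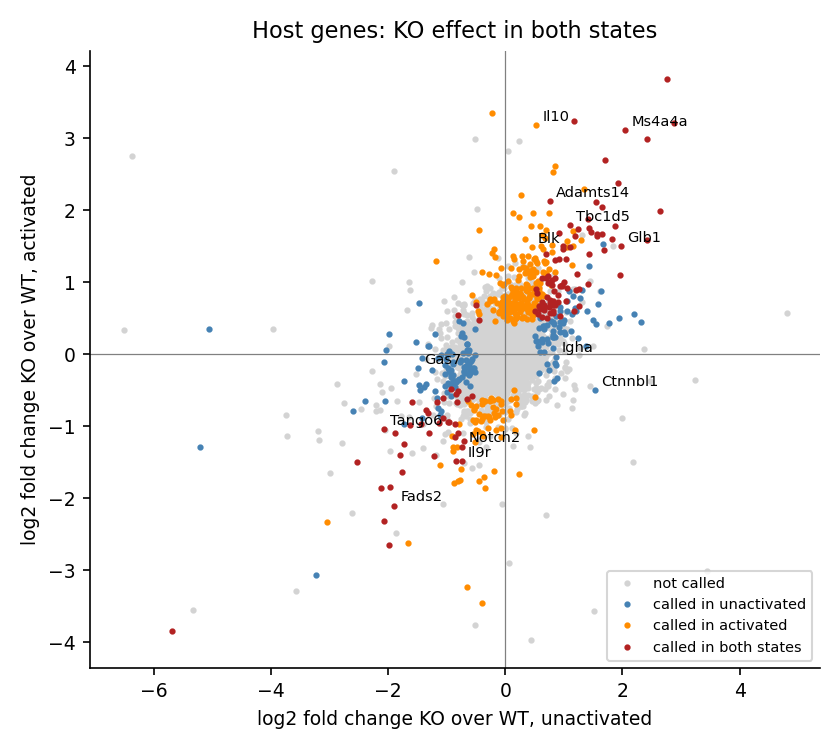
Fitted log2 change, KO over WT, of each of the 4485 gene values in unactivated (horizontal) and activated (vertical) cells. Colours mark in which state a gene value was called. 83 gene values were called higher in both states and 38 lower in both.

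Among gene lists fixed beforehand, the plasma cell program and B cell identity were called higher in activated KO cells at the preset correlation. Neither call held with an estimated correlation: adjusted p = 0.183 for the plasma cell program and adjusted p = 0.629 for B cell identity. Both held with the block for the replicate number. Of 8 measured plasma cell genes 2 rose and 0 fell, or 3 and 0 adjusted over the list alone (adjusted p of the list = 0.00832). Prdm1, which encodes the plasma cell regulator Blimp-1, rose by a log2 change of 1.32 ± 0.26, and Irf4 by 0.89 ± 0.18, while Ell2 stood at 0.53 ± 0.18 (adjusted p = 0.0563) and Cd38 at 0.49 ± 0.21 (adjusted p = 0.181). Ell2 lay near the threshold: it was called on leaving out any of 4 of the 12 libraries (0.59 to 0.61) and with the block for the replicate number (0.54). It was also called without the unactivated libraries that stand apart, a setting chosen after the data were seen (0.53). Cd38 was called on leaving out 1 library (0.75). Against parental WT alone neither Prdm1 (0.79) nor Irf4 (0.72) was called, and the call of Prdm1 was also lost with counts summed per line (1.23). Of 17 measured B cell identity genes 6 rose and 1 fell, or 7 and 1 adjusted over the list alone (adjusted p of the list = 0.0403). Blk, a kinase of the B cell receptor pathway, rose by 1.49 ± 0.17, Ebf1, a B lineage transcription factor, by 0.76 ± 0.20, Bank1 by 0.68 ± 0.20 and Bach2 by 0.53 ± 0.15. The call of Bank1 was lost on leaving out any of 6 of the 12 libraries and that of Bach2 on leaving out any of 3, with log2 changes from 0.49 to 0.79 and from 0.48 to 0.60. Ebf1 (0.74 to 0.78) and Bank1 (0.62 to 0.73) lost their calls with either KO line alone and against either WT line alone, and Bach2 with KO1 alone (0.44), against parental WT alone (0.38) and with counts summed per line (0.52). In unactivated KO cells no list passed, the lowest adjusted p being 0.0696 for the plasma cell program, of which Prdm1 rose by 0.92 ± 0.23.

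Activation of the WT lines changed more transcripts than loss of ZMYND8 did in either state, with 4472 up and 5664 down. Notch2 rose 5.09-fold, from 3.21 ± 0.334 to 16.5 ± 3.05 CPM (adjusted p = 2.29e-14). Cxcr5, the chemokine receptor that guides B cells to follicles, rose 5.02-fold and Il9r 5.27-fold. Sema4b, Cd82, Birc2, Xylt1, Zfp710 and B4galt1 had log2 changes from 2.12 to 2.42. Mcoln2, an endolysosomal cation channel, fell 5.28-fold, Gas7 4.76-fold and Adamts14 3.62-fold, and Myc fell 2.56-fold, from 25.4 ± 7.16 to 9.94 ± 1.90 CPM. Trappc6a, Zc3h12d, Cmah, Atp6v0e2, Plxnc1 and Plek had log2 changes from -1.82 to -1.21, and Trappc6a lost its call on leaving out any of 9 of the 12 libraries, with log2 changes from -2.58 to -1.52, and also with no low-count filter (-1.84) and in fits of only the WT libraries (-1.82) or of 2 groups (-1.75). Igha rose by 1.01 ± 0.13. Summed mu counts, which leave out annotated Ighm transcripts, fell by 1.31 on the log2 scale (exact permutation p = 0.00216, adjusted p = 0.00346). RNA of the 3' regulatory region was 7.09 ± 0.975 CPM with and 5.65 ± 1.15 CPM without activation, a ratio of 1.25 that missed the threshold after adjustment (exact permutation p = 0.0498, adjusted p = 0.0569). The lines differed: parental WT went from 6.49 ± 1.11 to 6.55 ± 0.677 CPM, the WT clone from 4.82 ± 0.112 to 7.62 ± 1.03 CPM (n = 3 each). Of its parts, hs3a (log2 change 1.27 ± 0.23) and those from 113235821 (0.96 ± 0.33) and 113240928 (0.86 ± 0.23) were called higher. The call from 113235821 was lost in several fits without 1 library. Not called were hs3b (-2.13 ± 0.95) and the parts from 113215821 (-0.12 ± 0.14) and 113248085 (0.68 ± 0.28).

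The gene lists that rose with activation of WT cells were targets of CD40 and NF-kB, targets of TGF-beta and SMAD proteins, and MHC class II presentation, and MYC with ribosome biogenesis fell, all at the preset correlation. None of these calls held with an estimated correlation: adjusted p = 0.183 for the first 3 lists and adjusted p = 0.113 for the fourth. All held with the block for the replicate number. Of 16 CD40 and NF-kB targets 12 rose and 1 fell, counts that were equal when adjusted over the list alone (adjusted p of the list = 9.02e-05). Fas, a death receptor, rose by 2.07 ± 0.22, Bcl2a1b, a survival factor, by 1.92 ± 0.19, Nfkbie by 1.88 ± 0.20 and Cflar by 1.16 ± 0.18. Of 10 TGF-beta and SMAD targets 7 rose and 0 fell, or 8 and 0 adjusted over the list alone (adjusted p of the list = 2.48e-05), with Smad7, the inhibitory SMAD, at 2.08 ± 0.23, Tgfbr2 at 1.21 ± 0.15 and Runx3 at 0.98 ± 0.14. Of 8 MHC class II genes 4 rose and 0 fell, or 6 and 0 adjusted over the list alone (adjusted p of the list = 0.00973), led by Ciita, the master activator of the class, at 2.04 ± 0.17, with Ctsh at 1.12 ± 0.20, H2-Aa at 1.02 ± 0.17 and H2-Eb1 at 0.92 ± 0.19. Of 5 MYC and ribosome genes 0 rose and 3 fell, or 4 fell adjusted over the list alone (adjusted p of the list = 0.00148). Wdr43 fell by 0.77 ± 0.19 and Gnl3 by 0.61 ± 0.14 on the log2 scale, and Polr1a stood at -0.63 ± 0.27 (adjusted p = 0.0996).

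Activation of the KO lines gave 4417 transcripts up and 4910 down. Dkk3, a secreted protein related to Wnt inhibitors, rose 8.28-fold, from 0.884 ± 0.118 to 7.35 ± 1.48 CPM (adjusted p = 5.03e-15). B4galt1, Xylt1, Ptpn12, Cd82, Ciita, Bcl2l15, Cxcr5 and N4bp1 had log2 changes from 2.22 to 2.68. Mcoln2 fell 5.48-fold, Cmah, which makes N-glycolylneuraminic acid, 4.66-fold, and Myc 2.35-fold. Il10, the regulatory cytokine, fell 2.44-fold, a call lost with counts summed per line (log2 change -1.33), and Ctnnbl1, Mdh1, Wnt10a, Colq, Rgs13 and Stk17b had log2 changes from -1.70 to -1.11. Igha stood at 0.11 ± 0.13 (adjusted p = 0.552). Summed mu counts, again without annotated Ighm transcripts, fell by 0.50 on the log2 scale (exact permutation p = 0.00216, adjusted p = 0.00346). RNA of the 3' regulatory region had a ratio of 1.22 with an exact permutation p of 0.182. That test did not pair cultures by replicate number. Taken by number, the activated sum lay above the unactivated one each time in both KO lines, by as little as 24.3 against 24.2 CPM in KO1 replicate 3. A paired test was not run. The same transcripts were called as in WT cells for 2705 that rose, against 397 if independent, and for 3418 that fell, against 558.

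The lists called in WT activation were called in KO activation too, at the preset correlation. None of these calls held with an estimated correlation: adjusted p = 0.113 for CD40 and NF-kB targets and adjusted p = 0.183 for the other lists. As in WT, all held with the block for the replicate number. Of 16 CD40 and NF-kB targets 13 rose and 0 fell, also when adjusted over the list alone (adjusted p of the list = 3.64e-06), with Nfkbie at 2.76 ± 0.21, Cd80, a costimulatory ligand, at 2.09 ± 0.31, Bcl2a1b at 1.63 ± 0.20 and Cflar at 1.60 ± 0.18. Of 10 TGF-beta and SMAD targets 8 rose and 0 fell by either adjustment (adjusted p of the list = 9.13e-05), with Skil at 2.40 ± 0.22, Smad7 at 1.91 ± 0.24, Ski at 1.68 ± 0.19 and Tgfbr2 at 1.42 ± 0.15. Of 8 MHC class II genes 6 rose and 0 fell, or 7 and 0 adjusted over the list alone (adjusted p of the list = 0.0124), with Ciita at 2.33 ± 0.17, Ctsh at 0.97 ± 0.21, H2-Aa at 0.80 ± 0.17 and Ctss at 0.70 ± 0.15. Of 5 MYC and ribosome genes 0 rose and 2 fell by either adjustment (adjusted p of the list = 0.0124). They were Myc and Wdr43, which fell by 0.50 ± 0.18 and lost its call on leaving out any of 9 of the 12 libraries (log2 changes from -0.59 to -0.45). Gnl3 stood at -0.30 ± 0.14 (adjusted p = 0.104) and Nop58 at -0.31 ± 0.21 (adjusted p = 0.316).

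The response to activation differed between genotypes for a smaller set, 399 transcripts with a higher and 210 with a lower change in KO than in WT. This set shrank steeply with counts summed per line and against parental WT alone, as given below for the processing. Il10 fell with activation from 3.01 ± 1.08 to 0.420 ± 0.457 CPM in WT and from 4.24 ± 1.42 to 1.72 ± 0.676 CPM in KO, a difference in log2 change of 2.66 ± 0.44 (adjusted p = 0.00204). The level in activated WT cells was low, with an SD above its mean, so the size of this fitted difference is uncertain. Against parental WT alone the difference was 0.97 and not called, and its call was also lost with KO1 alone (2.21) and with counts summed per line (1.74). Adamts14 fell from 20.7 ± 2.76 to 5.91 ± 1.86 CPM in WT and went from 35.3 ± 3.31 to 25.5 ± 6.65 CPM in KO, a difference of 1.36 ± 0.21 (adjusted p = 0.000519). Ctnnbl1 went from 2.20 ± 0.620 to 2.76 ± 1.09 CPM in WT and fell from 6.48 ± 1.89 to 2.03 ± 0.808 CPM in KO, a difference of -2.03 ± 0.28 (adjusted p = 6.74e-05). Igha rose in WT and had no call in KO, a difference of -0.89 ± 0.18 (adjusted p = 0.00875). Ptpn12, Gas7, Atp6v0e2, Abr and Dkk3 had higher changes in KO, by 1.01 to 1.35, and Coro2a and Zfp710 lower ones, by -0.87 and -1.10. On leaving out single libraries, Atp6v0e2 lost its call in 14, Dkk3 in 18 and Zfp710 in 15 of 24 fits. None of the 11 genes named in this paragraph kept its call against parental WT alone, and only Adamts14, Ctnnbl1 and Ptpn12 kept it with each KO line alone and against the WT clone alone. Gas7 and Atp6v0e2 had been lower in KO before activation. In all, 25 gene values had higher and 9 lower changes in KO. No gene list passed for the difference, with a lowest adjusted p of 0.126 for germinal centre markers.

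**Figure D4:**
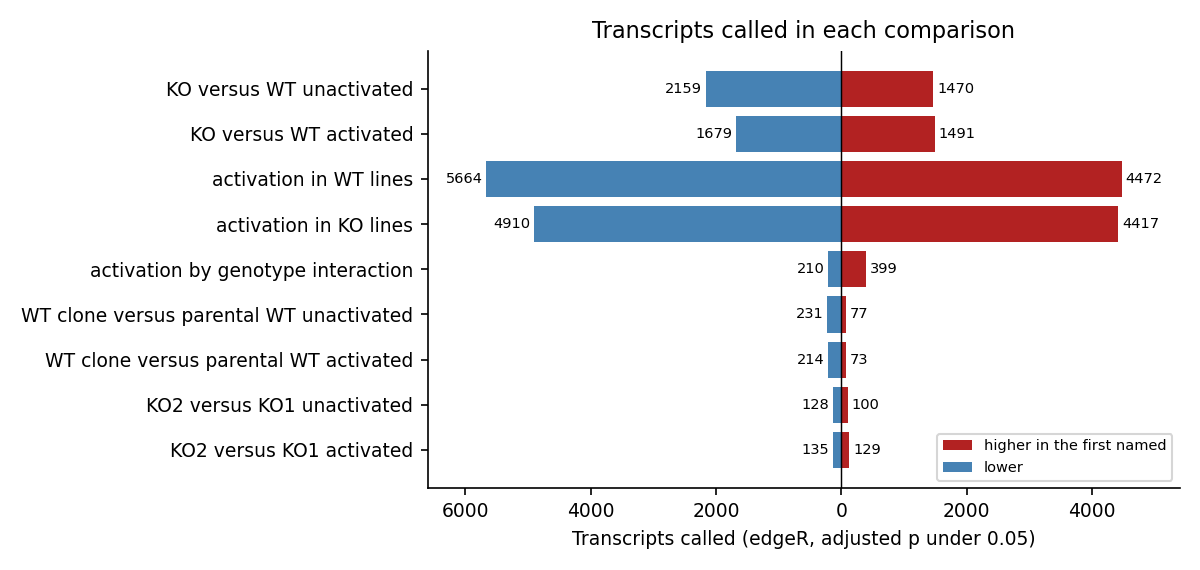
Transcripts called higher (right) and lower (left) in each comparison, out of 49806 tested with edgeR. Activation gave the most calls, KO against WT fewer, and lines of one genotype between 228 and 308. Lines of one genotype were compared with 3 against 3 libraries, KO against WT and activation within a genotype with 6 against 6.

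The remaining lists gave no call in any of the 5 main comparisons. The lowest adjusted p was 0.579 for class switch and hypermutation factors, 0.861 for IL-4 and STAT6 targets, 0.0696 for interferon-stimulated genes and for ATF4 and amino-acid stress, 0.235 for S phase and replication, 0.685 for mitosis, 0.176 for hypoxia and glycolysis, 0.131 for cholesterol synthesis, 0.126 for germinal centre markers and 0.818 for ZMYND8 partners with the NuRD complex. Lists with under 5 measured members were not tested. Of these, immediate-early genes had 4 measured, p53 targets 3, myeloid markers 2, Igh constant genes 1, fibroblast markers 1, and erythroid markers and mitochondrially encoded mRNAs 0. The fibroblast marker was called higher with activation, by log2 changes of 2.65 in WT and 2.15 in KO, and had no call between genotypes. Of 4 measured T and NK cell markers, Lck was higher in KO in both states (log2 changes 1.03 ± 0.29 and 1.33 ± 0.29), Il7r was higher in activated KO cells (1.52 ± 0.43), and Cd28 was lower in unactivated KO cells (-0.93 ± 0.26). Neither of the myeloid markers, Itgam and Itgax, was called in any of the 5 comparisons, and Trp53inp1, a p53 target, was higher in activated KO cells by 1.65 ± 0.25.

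Regions inside Zmynd8 itself had 1.90 ± 0.397 CPM in KO and 1.52 ± 0.262 CPM in WT without activation (log2 change 0.32 ± 0.17, adjusted p = 0.344), and 3.48 ± 0.671 against 2.43 ± 0.435 CPM with it (0.52 ± 0.16, adjusted p = 0.0392). The second call was lost on leaving out any of 7 of the 12 libraries, with log2 changes from 0.41 to 0.61. The edited part of the gene is not given in the sources used here, so these values neither show nor question the knockout.

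Fewer transcripts were called between lines of one genotype than between KO and WT, but with 3 against 3 libraries and not 6 against 6. At equal size, the 2 splits of the lines that mix genotypes called 224 and 354 transcripts in unactivated cells, against 3629 for KO and WT. In activated cells they called 158 and 406, against 3170. Between the WT clone and parental WT, 77 transcripts were higher and 231 lower in unactivated cells and 73 and 214 in activated cells. Between KO2 and KO1 the numbers were 100 and 128, and 129 and 135. These numbers depended on the tool: DESeq2 called 897 without activation (342 higher and 555 lower) and 872 with it (323 and 549) between the WT lines, and 642 and 742 between the KO lines. Log2 changes of KO1 over parental WT and of KO2 over the WT clone, which share no library, correlated across transcripts at Pearson r = 0.199 (Spearman rho = 0.270) in unactivated and 0.129 (0.198) in activated cells. For transcripts of at least 10 CPM r was 0.517 and 0.392. For the differences between lines of one genotype, KO1 over KO2 and parental WT over the WT clone, r was -0.0109 and -0.00438, and -0.205 in both states for transcripts of at least 10 CPM. Transcripts are not independent replicates, so no p is given. The 3 cultures of a line measure the spread between cultures only, and with 2 lines per genotype a difference between these lines that has nothing to do with ZMYND8 is covered by no p-value here.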

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

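The tests of scaling and of shared reads for the 3' regulatory region, and both tests on the unactivated WT libraries that stand apart, were chosen after those results were seen, as was the comparison of regions outside and inside genes; the other tests were fixed first. Groups of 3 libraries were not tested for outlying samples.

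The effect of activation differed between genotypes, by the interaction test, for 11 named genes and 5 Igh targets. The difference in log2 change, KO minus WT, was 2.66 for Il10, 1.36 for Adamts14, 1.35 for Ptpn12, 1.30 for Gas7, 1.10 for Atp6v0e2, 1.03 for Abr and 1.01 for Dkk3. It was -0.87 for Coro2a, -0.89 for Igha, -1.10 for Zfp710 and -2.03 for Ctnnbl1. Against parental WT alone none of the 11 kept its call, with 0.97 for Il10, 0.997 for Adamts14, 1.33 for Ptpn12, 0.88 for Gas7, -0.69 for Igha and -1.52 for Ctnnbl1 among them. At the Igh locus the difference was 1.18 for the region over Ighm, -1.32 for the mu enhancer and -0.89 for the region inside Igha. Reads shared between the region over Ighm and the mu enhancer are not excluded. For the regions near Ighg2b and Ighg3 the fitted differences were 7.11 and 3.46, but these set activated cells against 0 and 1 counts in unactivated KO cells, so they depend on the prior count of the fit. The difference near Ighg3 lost its call in 6 of 24 fits that left out single libraries, with KO1 alone (2.15), with KO2 alone (4.76), against parental WT alone (3.44), with no low-count filter (3.44) and without the 3 libraries that stand apart, a setting chosen after the data were seen (3.14). With counts summed per line all 5 Igh targets lost their calls.

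Higher RNA from the Igh 3' regulatory region in both KO lines was weighed against 3 explanations. On library totals alone the smaller of the log2 differences of the 2 states was 2.20 (2.1968). The scaling factors lay between 0.924 and 1.11, too close together to make or remove a difference of this size. The test could therefore not have come out otherwise, and shows only that these factors did not make the difference. Without any hs element the smaller difference was 2.22 (2.2151), which argues against reads shared between hs3a and hs3b as the whole cause. The hs elements held little of the sum, 25.9 CPM with and 24.3 CPM without them in unactivated KO cells, so leaving them out could change it little. The largest difference between lines of one genotype was 19.5% of the KO difference on the log2 scale, which argues against differences between single lines of the size seen here. An effect of ZMYND8 loss is a hypothesis that may account for the rise, with only 2 lines per genotype and no rescue measured.

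Regions called in activated KO cells rose more often than they fell, 633 against 152. Centring regions on their own median left 70.5% of calls higher, which argues against a shift of all regions relative to transcripts as the whole cause, and among regions of at least 2 CPM 77.7% of calls were higher, which argues against low regions that can only rise. More unspliced RNA stays open as a part of the cause: the share of counts in regions inside single genes was 1.11% ± 0.0819 in activated KO and 1.02% ± 0.0653 in activated WT libraries, a ratio of 1.09 (exact permutation p = 0.0519, n = 6 each), against 1.00 in unactivated cells (exact permutation p = 0.981). Regions outside genes, which unspliced RNA of the annotated genes would not raise, leaned at least as far, with 198 higher and 35 lower (85.0%) against 314 and 75 (80.7%) inside single genes. An effect of ZMYND8 loss on RNA from these regions was not tested apart from these.

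The third parental WT and the second WT clone culture, both unactivated, stood apart on the second principal component (13.9% of variance). Their deviation from the rest of the group correlated across transcripts with the activation effect at r of at most 0.0146, which argues against partial activation or a swapped state. Across transcripts it rose with transcript length, at a rank correlation of 0.342 and 0.203, so a length bias, as RNA quality could give, is a possible explanation. The rank correlation was 0.228 in the second activated parental WT culture, which on that component lay toward the same side of its group (-70.2 against -7.91 and -34.7), and the largest in size was -0.361, in the second unactivated parental WT culture. Without these libraries KO against WT gave 3808 transcripts in unactivated cells, and also without the second KO1 culture, which stood apart on the fourth component, 3379.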

How the results depend on the processing

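The fits without libraries that stand apart, and all alternatives for sums at the Igh locus, were chosen after the data were examined. No result changed direction while called, and a change of sign in a value called under neither setting was counted as unchanged. Of 269 settings other than leaving out single libraries, 210 left the main results on their side of the threshold or within 1.5 times the count, and of 408 that left out a library, 383. The KO differences of the 3' regulatory region and all 4 mu differences held under every scaling and left-out library tried. The causes of the changes below were not tested, except that fits on fewer lines or libraries have fewer samples.

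Counts summed per line left 309 transcripts and 54 regions for KO against WT in unactivated and 199 and 49 in activated cells, 3707 and 412 for activation in WT, 3500 and 535 in KO, and for the difference of activation 0 transcripts and 57 gene values. With KO1 alone, KO against WT gave 2159 transcripts, 425 regions and 158 gene values in unactivated and 1782, 392 and 184 in activated cells, and the difference of activation 220 transcripts and 14 gene values. With KO2 alone, it gave 463 regions and 184 gene values in unactivated cells, and the difference 255 transcripts and 19 gene values. Against parental WT alone, it gave 2358, 386 and 156 in unactivated and 2056, 399 and 193 in activated cells, and the difference 149 transcripts and 0 gene values. The 2-group fit gave 2252 transcripts and 430 regions for KO in unactivated cells and 1381 regions for activation in WT. With only the libraries of the comparison, KO gave 440 regions in unactivated cells, the WT lines differed in 5 and 11 transcripts and the KO lines in 112 and 101 in unactivated and activated cells. DESeq2 called 1549 transcripts for the difference of activation, 897 and 872 between the WT lines and 642 and 742 between the KO lines. Without a low-count filter, the difference of activation gave 333 transcripts and the activated WT lines 171. A replicate block gave 54 gene values for the difference. Without the 3 unactivated libraries standing apart it gave 19, and the activated WT lines 455 transcripts.

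The call for Zmynd8 in activated cells ended at log2 changes of 0.51 with no filter or line sums, 0.59 with KO1 alone, 0.45 with KO2 alone, 0.61 against parental WT alone and 0.43 against the WT clone alone. With an estimated correlation 0 of 10 gene list calls held, and with the replicate block 10. The correlation of KO1 and KO2 effects was 0.517 and 0.392 over transcripts of at least 10 CPM. Activation of the 3' regulatory region lost its unadjusted call in WT with relative log expression scaling (0.30) and in 9 of 12 fits without a library, and gained it in KO on library totals alone (0.40).

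Leaving out single libraries gave these lowest and highest values. For transcripts: 2829 to 3459 for KO in unactivated cells, 2591 to 2896 in activated cells, 8838 to 10281 for activation in WT, 8036 to 8819 in KO and 428 to 616 for their difference. For regions: 562 to 707, 607 to 708, 1822 to 2398 and 2180 to 2465 for the first 4. For gene values: 218 to 323, 296 to 374, 854 to 1172, 1057 to 1200, and 23 to 51 for the difference. In all 4 pairings: 473 to 575 in unactivated and 366 to 498 in activated cells. The unactivated WT lines ranged from 202 to 306 transcripts (202 without the first parental WT and 205 without the third WT clone culture), and the activated from 145 to 211 (187 without the first parental WT, 191 without the first and 145 without the second WT clone culture). The unactivated KO lines ranged from 143 (without the second KO2 culture) to 175, and the activated from 155 to 216 (167 and 165 without the first and second KO1, 155 without the first KO2 culture). Zmynd8 ranged from 0.20 to 0.40 and from 0.41 to 0.61 for KO in the 2 states, 0.57 to 0.75 and 0.76 to 0.99 for activation, and 0.09 to 0.32 for the difference. For KO, the 3' regulatory region ranged from 2.13 to 2.31 and from 2.05 to 2.23, and mu from -0.36 to -0.27 and from 0.44 to 0.56. For activation in WT and KO, the 3' regulatory region ranged from 0.25 to 0.44 and 0.18 to 0.35, and mu from -1.37 to -1.24 and -0.53 to -0.47.

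For named genes, 1340 of 1430 values under other settings stayed on their side of the threshold, 86 lost and 4 gained a call, and of 1752 with a library left out, 1657 stayed, 90 lost and 5 gained it. For Igh targets, 708 of 758 stayed, 46 lost and 4 gained a call (28 of the losses with line sums), and of 1008 with a library left out, 989 stayed. Counts of regions and gene values for lines of one genotype and for all 4 pairings, and of regions for the difference, were computed under the same settings and, after their values were seen, left out above for length. They are 13 results with 87 settings, of which 32 moved the count by over 1.5 times, and 120 left-out libraries, of which 45 did. The replicate number was not taken to pair the libraries: same-number pairs correlated at a median of 0.060 (23 of 84 above 0.1) and other pairs at -0.0308 (12 of 168 above 0.1). Still, 14 of 24 libraries correlated best with one of their own number, so a shared structure is not excluded. The summed 3' regulatory region was highest in replicate 1 of every group, as in activated KO2 with 42.9, 28.3 and 26.2 CPM for replicates 1 to 3. The permutation tests of Igh sums did not take the replicate number into account. The length-scaled, protein-coding and Igha share alternatives were not run. At these depths, elements with few counts, such as hs4, cannot show a difference.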

Other observations

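The list of regions outside genes and the tests by splits for KO against WT in unactivated cells, for the unactivated WT lines and for the 4 lines were chosen only after results were seen. The test at the Igk locus was written down before its value was seen.

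Of 2697 regions outside genes tested, 25 were higher and 1 lower in both KO lines against both WT lines in both states. Among the 16 of these with at least 5 CPM in a group, the 2 largest rises in activated cells lay on chromosome 16. They were at the Igl light chain locus, taken here with a margin of 50000 bases on each side. The region from 19010282 to 19012128 lay 39973 bases from Hira, its nearest named gene. It was at 17.4 ± 1.42 CPM in unactivated KO and 0.4997 ± 0.1635 CPM in WT, a log2 change of 5.12 ± 0.26, and of 5.08 ± 0.25 in activated cells. The region from 19023848 to 19026109, which lies 35643 bases from Iglc1, changed by 4.28 ± 0.18 and 4.34 ± 0.18, and that from 19178718 to 19180317, 18219 bases from Iglc2, by 2.96 ± 0.19 and 3.12 ± 0.19. The region over Iglc1 (19059420 to 19065940) went the other way, by -2.25 ± 0.14 and -2.87 ± 0.14, as did that over Iglc2 (19196554 to 19199126), by -1.09 ± 0.20 and -0.71 ± 0.19. Of 17 regions tested at the locus with this margin 7 rose and 3 fell in unactivated KO cells, and 6 rose and 4 fell in activated ones.

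On chromosome 10, a region 9526 bases from Chst3, a chondroitin sulfotransferase gene (60165989 to 60172001), was at 27.2 ± 4.67 CPM in unactivated KO and 1.86 ± 0.347 CPM in WT, and at 22.5 ± 1.22 against 1.53 ± 0.277 CPM in activated cells. On chromosome 11, a region 994 bases from Supt4a (87744617 to 87753828) was at 20.8 ± 5.84 against 6.96 ± 2.05 CPM in unactivated and 28.7 ± 8.20 against 7.93 ± 1.81 CPM in activated cells. A region 274910 bases from Myc on chromosome 15 (62265271 to 62268790) rose by 1.70 ± 0.18 and 1.28 ± 0.18 on the log2 scale, while Myc itself had no call between genotypes (-0.07 ± 0.17 and 0.06 ± 0.17).

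A hypothesis from some of the Igh and Igl regions is that ZMYND8 loss may raise RNA at antigen receptor loci in general, which would show at the Igk locus, although at the Igh locus itself 5 of 14 regions rose and 5 fell in unactivated and 5 rose and 4 fell in activated KO cells. At the Igk locus, taken with the same margin of 50000 bases, 5 of 28 regions tested rose and 2 fell in unactivated KO cells. So 17.9% rose (17.857, 95% Wilson interval 7.88% to 35.6%), against 3.70% of all regions. The interval takes the regions as independent, which neighbouring regions of a locus measured in the same lines are not. The share counts every region of the locus, so it does not test those beside the constant gene alone. The bound written before the value was seen, under 25%, would by the value alone speak against the hypothesis. A condition that the whole interval lie under that bound was added after the value was seen, and under it the test leaves the hypothesis open. In activated cells 7 rose and 1 fell, 25% of 28 (12.7% to 43.4%). Of the rises, the region from 68861770 to 68863377 changed by 3.73 ± 0.30 and 3.69 ± 0.39 in the 2 states. The region from 70743443 to 70744593, 16689 bases from Igkc, changed by 1.87 ± 0.22 and 1.85 ± 0.21, and that from 70749719 to 70752995 by 1.35 ± 0.17 and 1.84 ± 0.17. The region over Igkc (70723395 to 70729468) changed by -0.62 ± 0.10 in unactivated cells and stood at 0.03 ± 0.10 in activated ones.

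For each main comparison, 40 splits were drawn of the same libraries into groups of the same sizes, and for each count below only the real split, 1 of the 40, gave as many calls, so chance can be excluded at this number of splits for cultures taken as independent. They are not: the splits exchange single cultures between lines, so for KO against WT and for the difference of activation they do not exclude chance differences between lines. For KO against WT in unactivated cells the real split called 3629 transcripts, 709 regions and 288 gene values, and the highest other 53, 5 and 32. In activated cells the numbers were 3170, 785 and 397 against 197, 28 and 81. For activation they were 10136, 2150 and 989 in WT against 2229, 316 and 343, and 9327, 2592 and 1266 in KO against 1225, 178 and 338. For the difference of activation between genotypes the real grouping called 609 transcripts and 34 gene values, and the highest other 11 and 1. For lines of one genotype 10 splits are too few for a share under 0.05: the real counts were 308 and 287 for the WT lines and 228 and 264 for the KO lines in unactivated and activated cells, and the highest others 12, 6, 3 and 1. For the 4 lines, 3 splits are too few as well: 630 and 542 transcripts were called in all 4 pairings, and the highest others were 28 and 26, while KO against WT called 3629 and 3170 and the highest other split of lines 354 and 406. For gene values of the WT clone against parental WT in unactivated cells, 6 were called, 5 of 10 splits gave as many and the highest other gave 301, which points to a structure among these libraries.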
